A study of Rattus norvegicus with 11 samples.

How the data were processed

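Total RNA from the prefrontal cortex of 11 rats was labelled with Cy3 and hybridized to custom Agilent rat arrays of which 8 share a slide, 1 rat per array, per the labels' protocols and the series design text. Scans were made at 100% laser power and 30% photomultiplier gain, and intensities were extracted with Agilent Feature Extraction 9.1 and normalized by the authors with a linear per-array algorithm, per the labels' descriptions. The deposited intensity values are on a linear scale and all above 0; the formula of the linear step, any background subtraction and any flags for dim or saturated spots are not given in the sources used here. The authors' normalization left the arrays at different levels, with 75th percentiles from 49.6 to 201. Values of the Control replicate 1 array carried 2 decimals throughout, against at most 2.22% of values on any other array. Intensities of this kind have no read depth; the number of arrays limits the precision.

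The table holds 15207 probes under custom identifiers with no gene column, and the reference table of RefSeq genes contains none of them, so 0 probes have a gene symbol. The tests therefore used 1 row per probe. The gene lists fixed before the data were examined (immediate early genes, serotonin and stress axis genes, cell type markers and others) could not be scored, nor could genes be named, and at most 2 probes per direction are listed for each comparison.

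Each array was divided by its 75th percentile, because the percentiles differed by more than the limit of the planned rule for using values as deposited. Values were then raised to a floor of 0.05 of that percentile and taken to log2. The floor was placed after looking at the intensities, above the pile of lowest values that every array showed. The 2804 probes at the floor on all arrays were left out, which left 12403. Because the fold of a probe at the floor is a bound, it is written as at least so many fold. No filter on level was used otherwise.

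All 11 arrays entered one limma 3.58.1 fit (lmFit and eBayes, R 4.3.3) with 1 mean per group, and 3 two-sided tests were taken: MS against Control, DOI against Control and MS against DOI. The fit had 8 residual and 2.01 prior degrees of freedom. Probes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison are called. Listed probes are the 2 largest called changes per direction whose arrays do not overlap between the groups, and, where fewer than 10 probes passed, the 2 with the lowest p per direction, the first entries of a rule fixed before the data were examined. Each array is a different rat, so p-values measure the spread between rats; litters are not given in the sources used here, and rats that share a litter would make them too small.

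The fold changes of MS and DOI were compared by their correlation and covariance beside 100 simulations of unchanged groups against the same Control arrays, repeated with each array left out. These simulations drew each probe independently, so their ranges are too narrow for arrays whose probes move together. What choosing probes by MS against DOI gives by itself was simulated in 50 draws each with Control at the true level of DOI, at that of MS and with no differences, each MS to DOI difference being shrunk by its own error. Probes varied independently there, unlike in the arrays, and more were called than the 891 (1460 and 1480 on average). Group distances were tested by exact permutation. All splits of the arrays into sets of 3, 4 or 5 against the rest were searched for the number of probes whose levels do not overlap, and the leading set was used as a block and to give values within sets; p-values with this block are too small to the extent that the set was chosen on the same data.

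The fit was tested on simulated data with the measured means and spreads of the 12403 probes, in which probes with a mean above the 75th percentile were changed by known amounts, so it does not cover dim probes. Of probes changed 2-fold it called 68.2% for MS against Control, 72.7% for DOI against Control and 74.2% for MS against DOI, with 5, 11 and 3 false calls. Alternatives were other scalings, floors and filters, variance estimates, array weights, thresholds, the 2 groups alone, a block and leaving out each array; all were planned except the floor of 0.03, no floor, the filter to probes above the floor on all arrays and the sets, which were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.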

Results

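Messenger RNA of the prefrontal cortex was profiled in 11 adult rats with 1-colour Agilent microarrays, 1 rat per array. The rats formed 3 groups. The Control group held 3 undisturbed rats given saline, the DOI group held 4 undisturbed rats given DOI at 8 mg/kg, and the MS group held 4 rats with a history of maternal separation given saline. Maternal separation is an early-life stress model in which pups are taken from the dam for part of each day. It lasted 3 hours a day from postnatal day 2 to postnatal day 14, and adult tissue was taken at about postnatal day 60, 2 hours after the injection. DOI is a hallucinogenic amphetamine that activates serotonin 5-HT2 receptors. The table gave 15207 probes with custom identifiers that neither it nor the reference table pairs with genes, so every result below is a count of probes or the level of a probe, and no gene is named. A probe level is the log2 of intensity relative to the 75th percentile of its array, with a floor.

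The 75th percentile of the intensities ranged from 49.6 on the MS replicate 5 array to 201 on the DOI replicate 1 array, a 4.06-fold range. On each MS array 32.1% to 34.0% of the probes lay at the floor, against 28.2% to 30.9% on each DOI array, with no overlap. The Control arrays had 29.5% to 32.4%. Transcripts above the floor on every array of a group numbered 9736 probes in Control (3 arrays), 9763 in DOI (4 arrays) and 9004 in MS (4 arrays). Levels of the 8731 probes above the floor on all 11 arrays correlated between arrays at Pearson r of 0.955 to 0.991 across probes, which are not independent replicates. The median SD between rats of a group was 0.24 log2 in Control (n = 3), 0.19 in DOI (n = 4) and 0.27 in MS (n = 4). The 3 groups lay farther apart than the rats within them (pseudo-F 2.16, exact permutation test over 11550 arrangements, p = 0.00502), a test added after the data were seen. Taken by pairs, MS and DOI were separated at the smallest p the design allows (pseudo-F 3.06, exact permutation p = 0.0286, 0.0857 after Benjamini-Hochberg adjustment over the 3 pairs). MS and Control (pseudo-F 1.5, exact permutation p = 0.143) and DOI and Control (pseudo-F 1.91, exact permutation p = 0.0857) did not pass 0.05, and no pair did after adjustment.

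**Figure D1:**
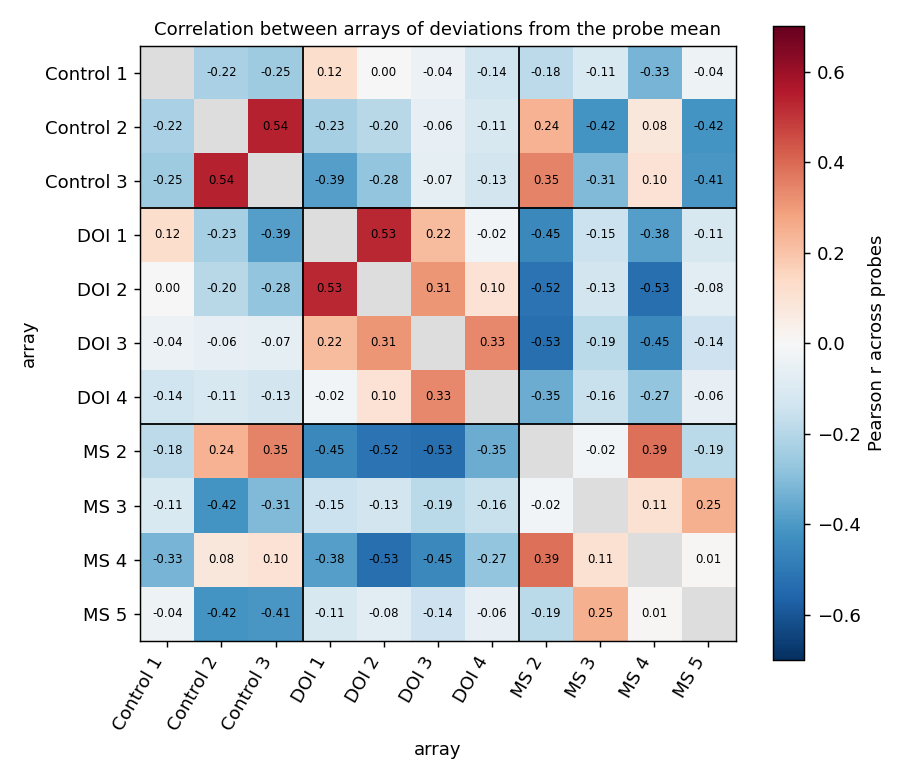
Pearson correlation across the 8731 probes above the floor on all arrays of each array's deviation from the probe mean, for every pair of the 11 arrays; black lines part the groups and the diagonal is left blank. The Control replicate 2 and 3 arrays correlate at 0.54 with each other and at -0.22 and -0.25 with the Control replicate 1 array.

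A set of 4 arrays stood apart from the other 7 across the groups. It comprised the Control replicate 2 and 3 arrays and the MS replicate 2 and 4 arrays, and 1314 probes, 15.1% of those above the floor on all arrays, had all 4 levels above or all 4 below the other 7. Of these probes, 644 were higher in the set of 4, by a median of 0.69 log2, and 670 were lower, by a median of 0.49 log2. No other split of 4 against 7 arrays parted more than 654 probes, the number parted by the 4 MS arrays. All 4 DOI arrays, the Control replicate 1 array and the MS replicate 3 and 5 arrays made up the larger set. The labels give no slide, date or litter, so the set was found in the intensities alone, and values within each set stand beside the pooled ones below.

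The adult cortex of maternally separated rats was compared with that of undisturbed rats, both given saline, to ask which transcripts differ after early stress. Of 12403 probes tested, 103 differed: 12 were higher in MS and 91 were lower (limma, Benjamini-Hochberg adjusted p under 0.05). With arrays centred on their median 2 were higher and 6 lower, quantile normalization gave 11 calls and a trended, robust variance 9, and none passed without scaling or in a fit of these 2 groups alone. Weighting arrays by their agreement with their group went the other way, with 459 calls, 102 higher and 357 lower, among them all 103. Control then rested mainly on replicates 2 and 3 (weights 2.96 and 1.93). The median change among the 103 was 0.68 log2 for the higher probes and -0.88 log2 for the lower ones, against a median standard error of 0.20 over all probes. At least 2-fold differences were found for 31 of the called probes, 2 higher and 29 lower. The calls lay mostly among weakly hybridizing probes: 88 of 8627 probes with a mean under the 75th percentile were called, 84 of them lower in MS, against 15 of 3776 brighter probes, 8 higher and 7 lower. The arrays of MS and Control overlapped in none of the 103 called probes and did not overlap in 12.7% of all tested probes, where chance gives 5.71% on average. Because probes move together, a single grouping can lie far from that average.

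The called probe with the largest increase, RN_GT_105577, had a level of 0.21 ± 0.88 (SD, n = 4) in MS against -2.10 ± 0.40 (SD, n = 3) in Control, a 4.96-fold difference (log2 2.31, SE 0.42; limma adjusted p = 0.0476). Its level in DOI was -1.59 ± 0.31 (SD, n = 4). RN_GT_115104 was 2.76-fold higher in MS (log2 1.46, SE 0.17; limma adjusted p = 0.0148), with -2.31 ± 0.25 (SD, n = 4) against -3.78 ± 0.23 (SD, n = 3). RN_GT_100090 was at the floor on all 4 MS arrays and at -2.26 ± 0.47 (SD, n = 3) in Control, so it was at least 4.18-fold lower in MS (limma adjusted p = 0.0216). RN_GT_105721 was at -4.25 ± 0.14 (SD, n = 4) in MS and -2.38 ± 0.29 (SD, n = 3) in Control, at least 3.67-fold lower (limma adjusted p = 0.0148), with 2 of the 4 MS arrays at the floor. With 1 array left out RN_GT_105721 passed each time, RN_GT_115104 failed without Control replicate 2 (adjusted p 0.018 to 0.0579 over the arrays left out), and RN_GT_100090 failed without Control replicate 2 or MS replicate 3 (adjusted p 0.0281 to 0.0579). RN_GT_105577 passed only without MS replicate 2 or 5 (adjusted p 0.027 to 0.154). Under the other alternatives RN_GT_105577 failed in 9 of 15, RN_GT_115104 in 4 of 15, RN_GT_100090 in 7 of 14 and RN_GT_105721 in 5 of 14.

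The count of MS differences depended on single rats. It fell to 5 without the Control replicate 2 array, to 20 without Control replicate 1, to 24 without Control replicate 3, to 10 without MS replicate 3 and to 22 without MS replicate 4, and it rose to 155 without MS replicate 2. Within the set of 4 arrays (2 MS, 2 Control) 26 probes passed, all lower in MS; within the set of 7 (2 MS, 1 Control) 573 passed, 327 higher and 246 lower, with the lone Control replicate 1 array assumed to vary like the other groups; with the sets as a block 247 passed, 52 higher and 195 lower, among them all 103. Of the 26 probes that passed within the set of 4, only 8 were among the 103. All 4 listed probes failed within that set (limma adjusted p 0.0565 to 0.222). The differences between MS and Control measured in the set of 4 and in the set of 7, which share no array, correlated at r = 0.21 (Spearman rho 0.27) across probes and had the same sign in 57.5% of them.

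The response to the 5-HT2 agonist was measured in undisturbed rats given DOI or saline. No probe passed the adjusted threshold with limma; the lowest adjusted p was 0.0582, and 1347 probes had an unadjusted p under 0.05, where 620 would be expected by chance. Differences of at least 2-fold were seen for 182 probes, 122 higher and 60 lower in DOI, and in 109 of these the DOI and Control arrays did not overlap. Of the 182, 37 lost most of their difference when 1 array was left out. Arrays of the 2 groups did not overlap for 13.2% of all tested probes (5.71% by chance), 1048 higher and 592 lower. Both chance values are averages without a spread. Probes move together across arrays, so a single grouping can lie far from them without an effect of DOI. The exact permutation test of the distance between these groups gave p = 0.0857. With arrays weighted by their agreement with their group, 738 probes passed, 405 higher and 333 lower in DOI. The Control replicate 1 array had the lowest weight of 0.33, and Control rested mainly on replicates 2 and 3 (weights 2.96 and 1.93). Both of these belong to the smaller set of arrays, which holds no DOI array. The weighted calls therefore cannot be told apart from a difference between the sets. With Control replicate 1 left out and no weights, no probe passed. A trended, robust variance in limma called 8 probes, all higher.

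The probes closest to the threshold were RN_GT_114561, at -3.15 ± 0.21 (SD, n = 4) in DOI and -4.21 ± 0.19 (SD, n = 3) in Control, at least 2.09-fold higher (limma adjusted p = 0.0582), and RN_GT_110876, at -0.76 ± 0.08 (SD, n = 4) against -1.41 ± 0.02 (SD, n = 3), 1.57 times as high (limma adjusted p = 0.0582). RN_GT_114561 was at the floor on 2 of the 3 Control arrays and on all 4 MS arrays, and it passed without the DOI replicate 3 array (adjusted p 0.0399 to 0.23 over the arrays left out). Among probes with lower values in DOI, RN_GT_101521 stood at -1.57 ± 0.14 (SD, n = 4) against -0.90 ± 0.14 (SD, n = 3; limma adjusted p = 0.142) and RN_GT_110348 at -2.47 ± 0.27 (SD, n = 4) against -1.44 ± 0.10 (SD, n = 3; limma adjusted p = 0.145). Within the set of 7 arrays 462 probes passed, 266 higher and 196 lower in DOI, but there the lone Control replicate 1 array is assumed to vary like the other groups; with the sets as a block none did. Under the other alternatives RN_GT_114561 passed in 3 of 12, RN_GT_110876 in 3 of 14, RN_GT_101521 in 2 of 14 and RN_GT_110348 in 1 of 14. These include array weights for each probe and, for the first 3 probes, the set of 7 with its lone Control array. In simulated data of the same size and spread, 72.7% of bright probes changed 2-fold and 7.35% of those changed by 0.5 log2 were called in this comparison.

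Maternally separated rats given saline and undisturbed rats given DOI differed at 891 probes, 236 higher and 655 lower in MS (limma, adjusted p under 0.05). Of these, 243 differed at least 2-fold, 21 higher and 222 lower. The direction varied with signal: among 188 called probes brighter than the 75th percentile 117 were higher in MS and 71 lower, and among 703 dimmer ones 119 were higher and 584 lower. It also varied with scaling, since centring arrays on their median in place of the 75th percentile gave 741 higher and 391 lower. The count depended on the processing too: 0 probes passed without scaling, 455 with no floor, 637 under quantile normalization and 1271 with array weights. Levels did not overlap between the 2 groups for 15.9% of tested probes, where chance gives 2.86% on average, a value without a spread for probes that move together.

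RN_GT_105577 was 3.47-fold higher in MS than in DOI (limma adjusted p = 0.0243). It failed without DOI replicate 2, 3 or 4 or MS replicate 4 (adjusted p 0.0107 to 0.0701 over the arrays left out). RN_GT_105255 was 3.37-fold higher (0.29 ± 0.90 in MS and -1.47 ± 0.55 in DOI, SD, n = 4 each; limma adjusted p = 0.0347) and failed without DOI replicate 2, 3 or 4 or MS replicate 2 or 4 (adjusted p 0.0229 to 0.088). RN_GT_100110 was 5.45-fold lower in MS, at -2.02 ± 0.53 against 0.42 ± 0.12 in DOI (SD, n = 4 each; limma adjusted p = 0.00316), with Control at -0.80 ± 0.48 (SD, n = 3). RN_GT_113325 was at least 4.25-fold lower, at -2.72 ± 1.12 against -0.63 ± 0.24 (SD, n = 4 each; limma adjusted p = 0.0247), with the MS replicate 5 array at the floor, and failed without DOI replicate 1, 2 or 3 or MS replicate 4 (adjusted p 0.00567 to 0.0717). RN_GT_100110 passed with each array left out. Under the other alternatives RN_GT_105577 failed in 4 of 14, the sets as a block and the set of 7 among them, RN_GT_105255 in 3 of 14, RN_GT_113325 in 2 of 13 and RN_GT_100110 in 1 of 14. Leaving out 1 array gave counts from 386, without DOI replicate 2, to 1041, without MS replicate 5; the counts were 413 without DOI replicate 3, 417 without MS replicate 4, 514 without DOI replicate 1 and 579 without MS replicate 2. Within the set of 7 arrays (2 MS, 4 DOI) 466 probes passed, 317 of them among the 891, and with the sets as a block 744 passed, 529 of them among the 891.

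**Figure D2:**
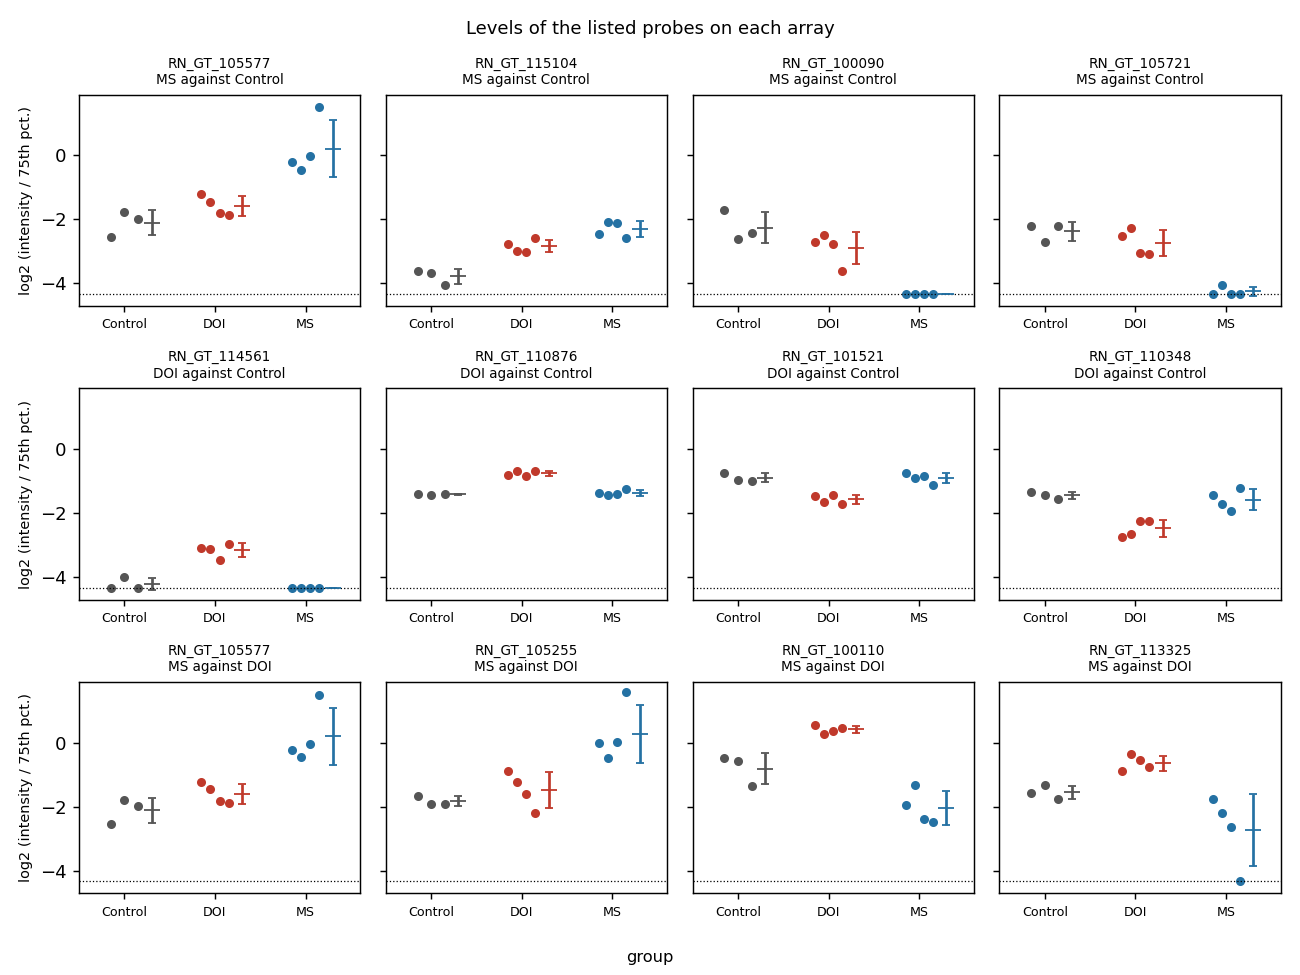
Level of each listed probe, log2 of intensity over the 75th percentile of the array, on every array of the 3 groups (points) with the group mean and SD (bars); the dotted line is the floor and the title gives the comparison that listed the probe. RN_GT_100090 lies on the floor on all 4 MS arrays, and RN_GT_100110 is at 0.42 in DOI and -2.02 in MS.

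The transcriptional differences of MS and of DOI from Control were then set against each other. They correlated at r = 0.30 (Spearman rho 0.25) across the 12403 probes, with a covariance of 0.0389, and had the same sign in 61.7%. Because both use the same 3 Control arrays, unchanged groups of this spread would give r = 0.57 (range 0.51 to 0.61 over 100 simulations), a covariance of 0.0483 (range 0.0424 to 0.0554) and the same sign in 69.3%. The observed covariance minus the simulated mean was -0.00939. With 1 array left out and the simulation repeated for the remaining arrays, this difference ran from -0.0232 to 0.011 and was above 0 without Control replicate 1 (0.011) and without MS replicate 2 (0.0107), so its sign depended on single arrays. The covariance lay below the simulated range in 8 of these 11 settings, within it in 1 and above it in 2. Probes varied independently in these simulations, unlike in the arrays, so the simulated ranges are too narrow. A value outside them does not show a departure from unchanged groups. With no array in common, taking MS against Control from the set of 4 and DOI against Control from the set of 7, the correlation was r = -0.15 (Spearman rho -0.14) and 41.9% of probes had the same sign. Every DOI difference there rests on the Control replicate 1 array alone, and the value has no estimate of its spread. The pooled value also rested on single arrays: r was 0.46 without Control replicate 1 and 0.18 without MS replicate 5, rho was 0.15 without MS replicate 3, and the covariance was 0.0639 without Control replicate 3. No probe was called in both comparisons, since none was called for DOI.

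The 103 probes called between MS and Control and the 891 called between MS and DOI had 92 in common, 7 higher and 85 lower in MS in both, where independent lists would share 0.23 higher and 4.81 lower ones. Both comparisons use the same 4 MS arrays, so part of the excess may come from them. In simulations with those arrays shared, at most 2 probes were in common where Control had the level of MS. At most 2 were called between MS and Control there, so the overlap could not be larger. Where Control had the level of DOI, 302 higher and 624 lower probes were in common on average. The Control mean lay between the MS and DOI means for 728 of the 891 probes (81.7%), which were chosen for their distance between MS and DOI. That choice by itself gave 62.1% in simulations with Control at the level of DOI and 61.3% with Control at the level of MS (highest of 50 draws each, 64.6% and 64.2%). Those simulations called 1190 and 0.2 probes on average between MS and Control, against the real 103, and more than 891 between MS and DOI. Their percentages are thus no upper limit for these data, and their overlaps cannot show how much of the 92 came from the shared MS arrays. Among the 655 probes lower in MS than in DOI, the median difference from Control was -0.58 log2 in MS and 0.26 log2 in DOI, where the simulations gave -0.04 in MS with Control at the level of MS and 0.05 in DOI with Control at the level of DOI. For the 236 probes higher in MS, it was 0.29 log2 in MS and -0.32 log2 in DOI, where the same simulations gave 0.06 and -0.05.

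**Figure D3:**
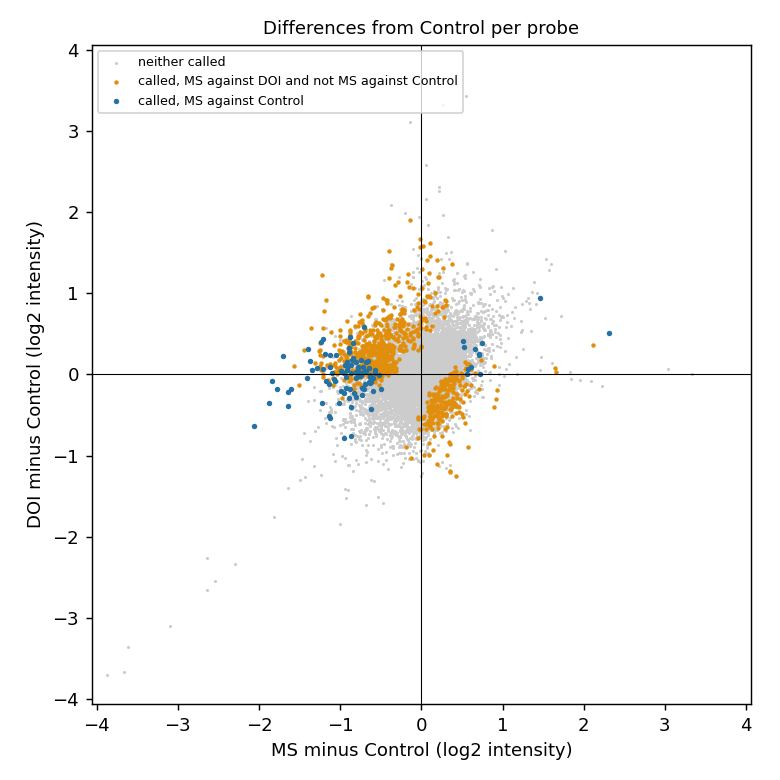
Difference from the Control mean of each of the 12403 tested probes in MS (horizontal axis, log2 intensity) and in DOI (vertical axis, log2 intensity); blue points are the 103 probes called between MS and Control, orange points those called only between MS and DOI, grey points the rest. Most orange points lie in the upper left and lower right quadrants, with Control between the 2 groups.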

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

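Of the tests in this part, those of slides, of too few Control arrays, of leaving out weak probes and of scaling, and the simulations of choosing probes, were chosen only after their results had been seen. Among 26 sets of 4 values tested for a value far from the others, 1 stood out, where chance gives about 1 in 20: RN_GT_105721 was at -4.04 on the MS replicate 3 array and -4.32 on the other 3 MS arrays, at the floor or next to it.

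The arrays of Control replicates 2 and 3 and MS replicates 2 and 4 stood apart from the other 7. Their highest deposited intensities did so too, at 65523 to 87907 against at most 54178 on the other 7. What raised these highest intensities was not tested. Overall brightness and its scaling are argued against as the cause of the parting. After quantile normalization 1231 probes were still parted, against at most 499 for any other split of 4 and 7. Weak signals are argued against too: 19.5% of the brighter probes were parted and 10.6% of the dimmer ones. One slide for each set could give this, since the larger set holds 7 arrays and a slide 8, but no label places arrays on slides, so it cannot be told apart from a difference between the rats such as dissection or litter. The set of 4 holds 2 of the 3 Control arrays, 2 of the 4 MS arrays and 0 of the 4 DOI arrays, so it is least balanced between DOI and Control and next between MS and DOI, where 529 of the 891 probes passed with the sets as a block.

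No probe was called for DOI against Control, beside 891 for MS against DOI. Too few Control arrays stays open. MS against DOI gave 386 calls in its lowest case with 3 arrays against 4, which shows only that such numbers allow calls. It held no Control array and more large differences, 401 probes of at least 2-fold against 182, so it cannot show that 3 Control arrays were enough. In simulated data, 7.35% of bright probes changed by 0.5 log2 were called in DOI against Control. A wider spread among the Control arrays was not decided by its planned test: their median variance was 1.49 times that of the DOI arrays. The fit pools 1 variance per probe over the 3 groups, so this spread entered all 3 comparisons. MS against Control has the same median standard error as DOI against Control (0.198) by design, with the same array numbers. It gave 103 calls, but chance is not excluded for that count. It therefore cannot decide whether the spread prevented calls for DOI. A biological candidate explanation is that DOI lies on the other side of Control from MS by less than the test can call. The Control mean lay between them in 81.7% of the 891 probes, against at most 64.6% in simulations of choosing these probes. Those simulations leave out what arrays share across probes and do not match the call counts of the data. They therefore set no upper limit and cannot decide this. Few of the 891 were set apart on both sides: at an unadjusted p under 0.05 in limma 522 differed from Control in MS only, 243 in DOI only, 68 in both and 58 in neither.

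Most probes called for MS were lower than in the other groups. Probes at the floor or in the dimmest 25% are argued against as the whole cause: without them 72.6% or 75.8% of the calls of MS against DOI and 92.3% or 91.9% of those of MS against Control were lower in MS. Weaker signals in general stay open, since these filters keep many dim probes and the planned test met its criterion: 37.8% of the called probes above the 75th percentile were lower in MS against DOI, and 7 of 15 in MS against Control. The scaling may also set the direction: for MS against DOI the lower share was 73.5% as reported, 67.5% under quantile normalization and 34.5% when arrays were centred on their median, while for MS against Control it stayed at 81.8% of 11 calls and 75% of 8 calls. The MS arrays also had more probes at the floor (32.1% to 34.0%) than the DOI arrays (28.2% to 30.9%). Whether this difference between arrays sets the direction was not tested. No biological explanation was tested for the direction either.

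For MS against Control, 2 of 35 splits of the 7 arrays gave as many calls as the real 103. The split that parted Control replicate 1 and MS replicates 3 and 5 from the rest, which follows the sets, gave 1262, and the next highest gave 29. The sets were chosen on these same arrays for the number of probes they part, so the 1262 calls are no further support for them. Chance is not excluded for the real count of 103, and with the sets as a block 247 probes passed, against 26 within the set of 4. For DOI against Control the real count of 0 is reached by all 35 splits whatever the data, so the count of splits says nothing about chance; the highest other split gave 1. For MS against DOI only the real split of 35 gave 891, the highest other giving 2, so chance can be excluded at 5% for this comparison alone, with no adjustment over the 3 comparisons.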

How the results depend on the processing

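Calls depended strongly on the processing for MS against Control, where the 103 became 11 under quantile normalization, 8 with median scaling, 37 without the dimmest 25% of probes, 9 with a trended, robust variance, 459 with array weights, 389 at an adjusted p under 0.1, and 0 without scaling, with the 2 groups alone or with the replicate number as a block. Alternatives added after the data were seen gave 61 with a floor of 0.03, 8 with no floor, 26 with only probes above the floor on all arrays, 26 within the set of 4 arrays, 573 within the set of 7 and 247 with the sets as a block; 1 array left out gave 5 to 155. A floor of 0.1 (112) and a minimum of 1.5-fold (95) stayed within 1.5 times. For DOI against Control the count of 0 became 8 with a trended, robust variance, 738 with array weights, 11 with a floor of 0.1, 9 at an adjusted p under 0.1, 462 within the set of 7 arrays and 0 to 1 with an array left out, and it stayed 0 with the replicate block. For MS against DOI the 891 became 0 without scaling, 437 with the replicate block, 455 with no floor, 1640 at an adjusted p under 0.1, 466 within the set of 7 and 386 to 1041 with an array left out; its 11 other alternatives with all of its arrays stayed within 1.5 times, although median scaling turned its direction (741 higher, 391 lower). Without scaling, the median probe shifted by -0.65 log2 in MS and -0.30 in DOI against Control, which shows the unequal array levels. The correlation of the MS and DOI differences was 0.43 (rho 0.45, covariance 0.0684) without scaling, 0.18 to 0.46 (rho 0.12 to 0.42, covariance 0.0244 to 0.0782) with an array left out, and reversed to -0.15 (rho -0.14, covariance -0.0303) with no shared array. The lowest of each came without MS replicate 5 and the highest without Control replicate 1. The 12 listed probe results kept their direction in all 255 alternatives, of which 56 lost and 10 gained significance. Listing required arrays that do not overlap between the groups, so leaving out an array could not reverse a direction. Arrays with the same number are different rats; their deviations correlated at -0.18 to 0.23, above 0.1 in 3 of 8 pairs, and 2 of 11 arrays matched their own number best. The gene list tests and the mean over probes of a gene were not run because the files pair no probe with a gene, and every probe on its own is the test reported. The cause was not tested except where named. Without background flags, the share of probes above true background is unknown.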

Other observations

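All counts in this part were chosen after the data were seen. Single arrays carried large signals that no other array showed. With 1 array per rat and no spot flags, a signal of the rat cannot be told apart from a fault of the spot. The DOI replicate 4 array had 9 probes more than 16-fold above all other arrays, Control replicate 2 had 8, MS replicate 3 had 6 and MS replicate 2 had 2. The largest gaps were 11.5 log2 on DOI replicate 4, 11 on Control replicate 2 and 13.3 on MS replicate 3. No array had a probe more than 16-fold below the rest, but the floor limits how far a dim probe can fall. At a 2-fold bound, DOI replicate 2 had 118 probes above all other arrays and Control replicate 1 had 55 above and 69 below. Pairs of arrays from different groups also shared probes at least 2-fold outside the other 9: Control replicate 1 and MS replicate 5 had 13 such probes above and 2 below, and DOI replicate 4 and MS replicate 5 had 2 above and 12 below.

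Probes with consecutive identifiers moved together. Over 5664 such pairs above the floor on all arrays the median correlation was 0.19, and 9.3% of pairs (527) had r over 0.9, against at most 0.494% in 100 random pairings. Both members of 33 such pairs were called between MS and DOI, so called probes need not be independent measurements.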
